A study of Drosophila sechellia and Drosophila melanogaster and Drosophila simulans with 24 samples.

How the data were processed

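The study measured RNA in single nuclei from the central brains of mated female flies by droplet sequencing (10x Genomics Chromium, 3ʹ chemistry). Per the labels, each library pooled nuclei from 20 brains, which were dissected after sorting by sex on day 5 and flash-frozen. The 24 libraries form 4 groups of 6: D. melanogaster (strain Canton S), D. simulans and D. sechellia on standard food, and D. sechellia on food with noni, the fruit that this species lives on.

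Per the file headers, Cell Ranger 5.0.1 wrote the matrices of replicates 1 to 4 and Cell Ranger 6.0.1 those of replicates 5 and 6, in every group, while the submitters' processing notes name version 6.0.1 alone. The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization, for barcodes already limited to called cells. The genome builds are not given in the sources used here. The D. melanogaster gene table holds 17875 genes, and D. simulans and D. sechellia share a table of 15384 genes; 13179 gene symbols are in both. Comparisons between species used the shared symbols, which held 85.95% to 88.3% of the UMIs of a library, and the diet comparison used the whole table of D. sechellia. A comparison with D. melanogaster therefore cannot be separated from a difference between gene tables. D. sechellia and D. simulans share 1 gene table, but whether their reads were mapped to 1 genome is not given.

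Total UMIs per library ranged from 12800608 to 29567533, the median per barcode from 1316 to 2303 UMIs and from 754 to 1018 genes, and the barcodes per library from 5101 to 12680. Nuclei were kept with at least 500 UMIs, at least 300 genes, under 5% of UMIs from mitochondrially encoded genes and no doublet call. Since the lowest barcode of a library held 481 to 502 UMIs, the UMI minimum removed few barcodes. The shared D. simulans and D. sechellia table names 1 mitochondrially encoded gene against 38 in that of D. melanogaster, so the mitochondrial limit acts mainly on D. melanogaster. Doublets were called per library from simulated doublets in 30 principal components of 1500 genes with 40 neighbours, marking 0.8% per 1000 barcodes (4.08% to 10.15% of a library). This left 201465 nuclei, 4892 to 11381 per library.

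Kept nuclei were clustered together on 2000 variable shared genes, with log counts centred and scaled per library, 50 principal components, 20 neighbours and Leiden clustering (igraph 0.11.9, resolution 3), giving 160 clusters. Clusters were named by marker lists written before the data were examined. Clusters with repo of at least 100 CPM (counts scaled to library size) were glia, named by the glial subtype with the highest median level of its markers. Fat body needed 3 markers raised at least 4-fold, and neurons were Kenyon-like, monoaminergic-like, neuroendocrine-like or named by a leading transmitter whose level was at least 0.5 of that in strong clusters. The level thresholds of this naming were set after the clusters had been seen. Neurons without 1 leading transmitter, and neurons of clusters whose leading genes held more markers of a further class than of their own, form the class of other neurons. The latter include clusters with a high transmitter level, such as cluster 93 with VGlut at 3901 CPM, and cluster 7 with 5846 nuclei, led by a marker of the trachea. The mixed or unnamed class, which is part of the whole-brain sums and of all kept nuclei but was not compared by itself, held 0.705% ± 0.493 of nuclei in D. melanogaster, 0.899% ± 0.588 in D. simulans, 0.863% ± 0.842 in D. sechellia on standard food and 0.754% ± 0.895 on noni (SD, n = 6). Different clusters hold some glial classes in the species: ensheathing-like nuclei of D. melanogaster lie mostly in cluster 29 and those of the other species in cluster 10, and perineurial-like nuclei in clusters 81 and 59.

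Counts were summed over all kept nuclei of a library (whole brain) or over a class, for classes with at least 30 nuclei in every library of the fit. edgeR 4.0.16 (R 4.3.3) tested genes with trimmed mean of M-values normalization, its low-count filter and the quasi-likelihood F-test, which is two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 3 species were fitted together on the 18 standard-food libraries, and the diets on the 12 D. sechellia libraries. An interaction term asked whether a difference between groups differs between glia and neurons. Class shares, in percent of kept nuclei, were compared by exact two-sided permutation tests of the difference in means (6 against 6, every assignment, scipy 1.17.1), adjusted over classes. The distance of a D. sechellia or D. simulans library from D. melanogaster was 1 minus the Pearson correlation across genes of log2(CPM + 1), on equal numbers of nuclei per library. Gene lists written before the data were examined were tested with limma 3.58.1 camera (preset correlation of 0.01, lists with at least 5 tested members), with an estimated correlation and with fry. The lists cover neuropeptides and their receptors, fast transmitter receptors, monoamine genes, chemosensory receptors, odorant-binding proteins, cytochrome P450s, glutathione and glucuronosyl transferases, Osiris genes, immune effectors, heat shock genes, activity-regulated genes, clock genes, nuclear and mitochondrially encoded genes of oxidative phosphorylation, cytosolic ribosomal proteins, glycolysis, sugar transport, lipid metabolism, IgSF recognition molecules, synaptic vesicle genes, voltage-gated channels, yolk and fat body genes, sex determination, blood-brain barrier genes and transmitter recycling.

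The rule for naming genes was also written before the data were examined. For whole brains it took called genes with a mean of at least 20 CPM in the higher group and no overlap between the libraries of the groups, and of these the 8 with the largest fold in each direction. It added up to 3 called members per list, 3 genes per direction in each class, and always ple, Ddc, Catsup, repo and elav; genes with only a number for a symbol gave way to the next named gene. The text prints a part of the genes so chosen. Chance gives no overlap in 0.216% of assignments of 12 libraries to 2 groups of 6. Where a group had 0 counts, the fold was computed against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% counting interval; floors and intervals cover counting error only.

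The libraries of a replicate number resemble each other. Over 5849 genes, deviations from the group mean correlated between same-numbered libraries at 0.363 to 0.846 for the diets, 0.323 to 0.737 for D. sechellia and D. simulans, 0.223 to 0.577 for D. sechellia and D. melanogaster and 0.21 to 0.589 for D. simulans and D. melanogaster, against medians of -0.158 to -0.103 for libraries of other numbers. Every comparison was therefore also run with replicate number as a block, and within replicates 1 to 4 and 5 to 6. The other alternatives tried were DESeq2 1.42.0, relative log expression size factors, no low-count filter, 1000 UMIs per nucleus, doublets kept, a Leiden resolution of 5, other clustering genes, equal numbers of nuclei, other correlations and pseudocounts, and leaving out each library. The calling was tested on simulated data with planted changes. The simulated libraries were drawn independently, without the resemblance by replicate number, so recovery in the real libraries may differ. In whole brains of the diet comparison, 54% of 1.5-fold, 88% of 2-fold and 96% of 4-fold changes were recovered, against 6%, 34% and 66% in perineurial-like nuclei, the class with the fewest nuclei tested.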

Results

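The data are counts of RNA molecules in single nuclei of the central brain of mated female flies from 3 Drosophila species. D. sechellia lives on noni fruit, while D. simulans, its close relative, and D. melanogaster are food generalists. There were 6 libraries each of D. melanogaster, D. simulans, D. sechellia on standard food and D. sechellia on noni, with 12800608 to 29567533 UMIs per library and 442875984 UMIs in all. The 201465 kept nuclei comprised 186485 neurons, 12435 glia and 2545 others. Glia made up 8.05% ± 0.866 of nuclei in D. melanogaster, 6.08% ± 0.955 in D. simulans and 5.25% ± 1.17 in D. sechellia on standard food (SD, n = 6). Levels below are means of scaled counts (CPM) with the SD over 6 libraries, and log2 fold changes and adjusted p are from edgeR. Between species, CPM were scaled to the UMIs of the shared symbols, and between diets to those of the whole table of D. sechellia. A D. sechellia library on standard food therefore has different CPM for a gene in the species and diet comparisons. Levels on noni can be set only against the standard-food levels of the diet comparison.

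The comparison of D. sechellia with D. simulans on standard food asks how the brain of the specialist differs from that of its generalist relative. Perineurial-like glia, the outer layer of the blood-brain barrier, made up 0.569% ± 0.178 of nuclei in D. sechellia and 1.05% ± 0.0616 in D. simulans (SD, n = 6), a ratio of 0.544. The exact permutation p was 0.00217, the smallest that a comparison of 6 with 6 libraries can give, and 0.026 adjusted over 12 classes, with a lower share in 6 of 6 same-numbered pairs. The difference (D. sechellia vs D. simulans) was -0.464 percentage points in replicates 1 to 4 and -0.503 in replicates 5 and 6. Without any 1 of the 6 D. simulans libraries the class missed the threshold (exact adjusted p up to 0.0779), although the libraries still did not overlap. The paired exact sign-flip test with replicate number as a block gave p = 0.0313, the smallest of its 64 flips, and 0.188 adjusted. Among nuclei with at least 1000 UMIs the difference was -0.194, with an exact adjusted p of 0.887, and after clustering without the leading genes that differed between species it was -0.335 (0.0779). No other class passed the threshold. Other neurons, at 27.0% ± 0.648 in D. sechellia and 26.3% ± 0.663 in D. simulans, were higher in 6 of 6 same-numbered pairs (paired exact sign-flip p = 0.0313, 0.188 adjusted; exact adjusted p = 0.584 unpaired). Astrocyte-like glia made up 1.63% ± 0.436 in D. sechellia and 1.95% ± 0.452 in D. simulans (exact adjusted p = 0.739), and ensheathing-like glia 2.67% ± 0.648 and 2.63% ± 0.438 (exact adjusted p = 0.9, n = 6).

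**Figure D1:**
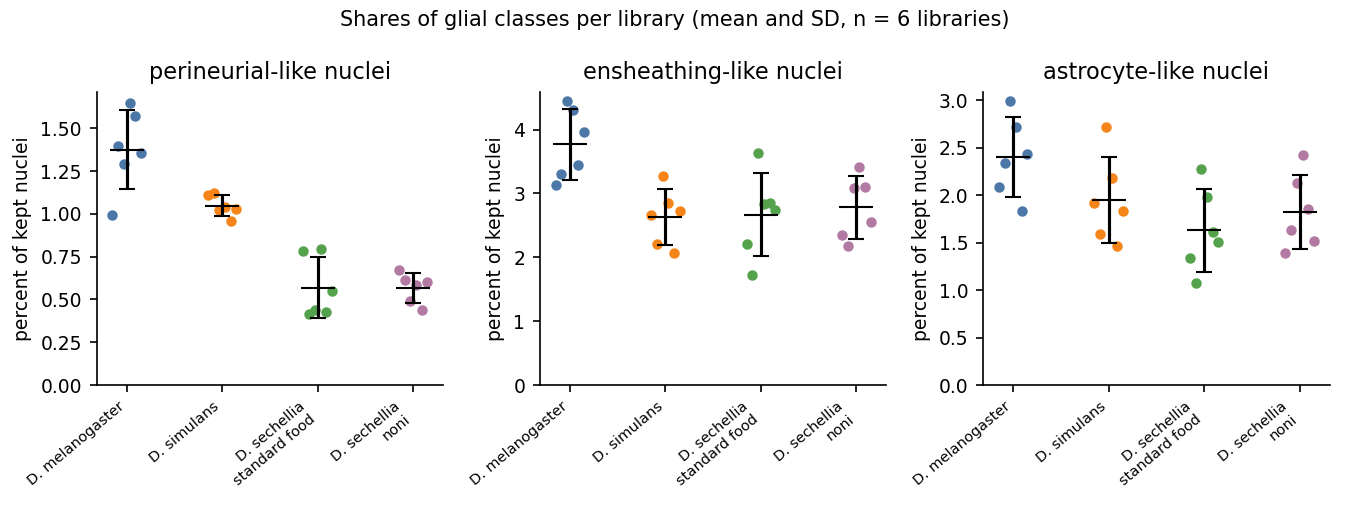
Percent of kept nuclei in each of 3 glial classes (y axis), for the 4 groups (x axis); points are libraries, and black marks give the mean and SD of 6 libraries. Perineurial-like shares of D. sechellia on standard food ranged from 0.417% to 0.795%, all below the 0.957% to 1.12% of D. simulans.

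Genes that stood highest in D. sechellia over D. simulans include receptors, enzymes and a growth factor. The G-protein coupled receptor gene mthl3 stood at 154 ± 24.8 CPM against 3.30 ± 0.344 (log2 fold change of 5.52, edgeR adjusted p = 9.66e-17), the glucuronosyl transferase gene Ugt50B3 at 78.2 ± 10.5 against 0.963 ± 0.913 (6.33), and the ionotropic receptor gene Ir40a, known from humidity sensing, at 32.5 ± 6.48 against 0.733 ± 0.24 (5.44). Pvf1, which encodes a ligand of the PDGF and VEGF type, rose from 1.56 to 44.3 CPM, Axs from 4.18 to 98.1, the glycosylation gene Alg14 from 11.9 to 110.4 and the acyl-CoA dehydrogenase gene Arc42 from 6.61 to 56.9. The detoxification gene Cyp6g1 (log2 fold change of 2.51) and the hormone receptor gene ETHR (2.18) were also higher. In the other direction, the laminin gene LanB2 stood at 0.809 ± 0.657 CPM in D. sechellia and 113 ± 18.4 in D. simulans (-7.14, edgeR adjusted p = 3.57e-13). Another ionotropic receptor gene, Ir67b (-3.62), the glycine transporter gene GlyT (-2.51) and the vesicle GTPase gene Rab26 (-2.07) were lower, the last at 473 ± 81.2 against 1980.0 ± 356 CPM. The integrin gene mew (-1.66), the metallothionein gene MtnA (-1.58) and the glutathione transferase gene GstD9 (-1.54) were lower too. LanB2 and Ir67b also stood higher in D. simulans than in D. melanogaster, which has its own gene table (values below). Their differences can therefore not be read as a loss in D. sechellia.

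Of 30 monoamine genes 9 were called higher and 1 lower (9 and 1 adjusted over the list alone), and camera did not call the list (adjusted p = 0.361). The tyramine receptor gene TyrR stood at 242 ± 91.6 CPM in D. sechellia and 89.4 ± 16.4 in D. simulans (n = 6; log2 fold change of 1.43, edgeR adjusted p = 0.000335). Tbh, whose enzyme turns tyramine into octopamine, was 1.51-fold higher. The dopamine synthesis genes ple (53.1 against 49.5 CPM, edgeR adjusted p = 0.487) and Ddc (797 against 790, 0.96) did not pass the threshold in whole brains, although Ddc did in monoaminergic-like nuclei (0.61, edgeR adjusted p = 0.0014). Catsup was higher by 0.32 (edgeR adjusted p = 0.0114) and elav by 0.33 (0.0164), and the glial gene repo was lower (-0.44, 0.0194). In replicates 5 and 6 alone Catsup, elav and repo did not pass, and without D. sechellia replicate 1 the adjusted p of elav was 0.062. The clock gene per (0.67), the adhesion gene side-VIII (0.81) and the calcium sensor gene Syt7 (0.76) were higher, and the neuropeptide gene spab (-0.94), the glutamine synthetase gene Gs1 (-0.69) and the sex determination gene dsx (-0.88) were lower.

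Cytosolic ribosomal protein genes were lower in D. sechellia, 43 of 78 members being called lower and 0 higher by edgeR (49 and 0 adjusted over the list alone), as were those of nuclear oxidative phosphorylation, with 40 lower and 3 higher of 68 (41 and 4 adjusted over the list alone). RpS26 (log2 fold change of -1.01), RpL5 (-0.69), COX8 (-0.97) and ND-B14.7 (-0.9) were among them. RpS26 was also higher in D. simulans than in D. melanogaster (values below). camera with its preset correlation called both lists (adjusted p = 2.69e-06 and 2.23e-05), with adjusted p = 0.943 for each with an estimated correlation. Of the glycolysis genes 9 of 16 were lower and 1 higher (10 and 2 adjusted over the list alone). Among them Pglym78 stood at 80.4 against 157 CPM and Tpi at 76.6 against 121. For glycolysis camera gave an adjusted p of 0.361, and of 0.0482 with the replicate block. With an estimated correlation, run without the block only, camera called 0 lists between these species. Chemosensory receptors were called higher and lower in equal numbers (13 and 13 of 43), whereas odorant-binding proteins were lower in 6 of 14 members and higher in 1.

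No other list passed camera. Their members called higher and lower were 5 and 6 of 36 for cytochrome P450s, 7 and 10 of 30 for glutathione and glucuronosyl transferases, 4 and 9 of 30 for lipid metabolism, 3 and 4 of 12 for sugar transport, 2 and 5 of 18 for heat shock genes, 2 and 1 of 14 for immune effectors, and 0 and 1 of 6 for yolk and fat body genes. For neuronal lists they were 2 and 3 of 39 for neuropeptides, 3 and 9 of 37 for their receptors, 5 and 3 of 31 for fast transmitter receptors, 4 and 5 of 27 for voltage-gated channels, 3 and 6 of 19 for synaptic vesicle genes, 9 and 4 of 64 for IgSF molecules, 1 and 1 of 13 for activity-regulated genes and 2 and 0 of 11 for clock genes. They were 1 and 3 of 11 for sex determination, 3 and 7 of 25 for blood-brain barrier genes, 1 and 8 of 15 for transmitter recycling and 1 and 0 of the 2 Osiris genes, too few for camera, as was the 1 mitochondrially encoded gene, which was not called. The test and the median or mean differed in sign for activity-regulated genes, fast transmitter receptors, heat shock genes, immune effectors, neuropeptide receptors, synaptic vesicle genes and voltage-gated channels.

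In all, edgeR called 3673 of 8716 genes between these species, 1865 higher and 1808 lower in D. sechellia, of which 549 and 420 differed at least 2-fold. It called 3021 in replicates 1 to 4, 2480 in replicates 5 and 6 and 4743 with the replicate block. Of the 87 genes named by the rule, 81 and 69 kept their side of the threshold in replicates 1 to 4 and in replicates 5 and 6, and 0 reversed. Apart from those always named, the rule picked these genes by their values in the same libraries. Here and in the comparisons below, such agreement therefore does not speak for the other calls. The genome or genomes behind the shared gene table are not given in the sources used here. A difference between the species in how reads were assigned to a gene is therefore part of each value.

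By class, mthl3, Ugt50B3 and LanB2 led in most kinds of neuron, while other genes led in glia. In Kenyon-like neurons of the mushroom body, Axs was at least 176.8-fold higher in D. sechellia, the mitotic kinase gene aurA at least 38.9-fold higher and LanB2 at least 147.5-fold lower. GABAergic-like neurons had mthl3 at 176 ± 27.5 CPM against 0.445 ± 0.405 (SD, n = 6), and glutamatergic-like neurons a ratio of 616 (170 to 5090). Monoaminergic-like neurons had GlyT at 107 ± 22.9 CPM against 874 ± 273 (log2 fold change of -3.01, edgeR adjusted p = 1.4e-12). In astrocyte-like glia, side-VIII stood at 2161 ± 331 CPM against 141 ± 73.7 (3.91, edgeR adjusted p = 1.4e-13), the collagen receptor gene Ddr at 588 against 47.8 and the calcium channel gene Ca-alpha1T at 1999 against 246, while the cuticle matrix gene dpy was lower, at 62.4 against 611. No background RNA was subtracted, and the neuronal gene elav stood at 664 and 565 CPM in astrocyte-like glia against 1023 and 807 in whole brains, so glial values hold RNA that cannot be assigned to glia. In ensheathing-like glia, Ddr stood at 1511 ± 197 CPM against 75.5 ± 26.4 and gukh at 216 against 8.83, and mol was at least 107.5-fold lower. Perineurial-like glia had the planar polarity gene pk at 1655 ± 822 CPM against 52.2 ± 40.4 (n = 6; edgeR adjusted p = 4.2e-08), the carbonic anhydrase gene CAH2 at 582 against 28.7 and CAH3 at 81.5 against 816.

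The number of genes called per class ran from 180 in perineurial-like glia and 394 in astrocyte-like glia to 2480 in other neurons and 2705 in cholinergic-like neurons. There were 1940 in GABAergic-like, 1573 in glutamatergic-like, 1466 in Kenyon-like and 533 in monoaminergic-like neurons, and 576 in ensheathing-like glia. With 30 nuclei per library and class the order was another, from 102 in GABAergic-like, 99 in Kenyon-like and 94 in astrocyte-like nuclei to 43 in other neurons. These nuclei were drawn once at random, and their UMIs were not equal. In D. sechellia replicate 1 on standard food they held 65411 UMIs in GABAergic-like and 19351 in astrocyte-like nuclei. Neither order therefore ranks the classes at equal depth.

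**Figure D2:**
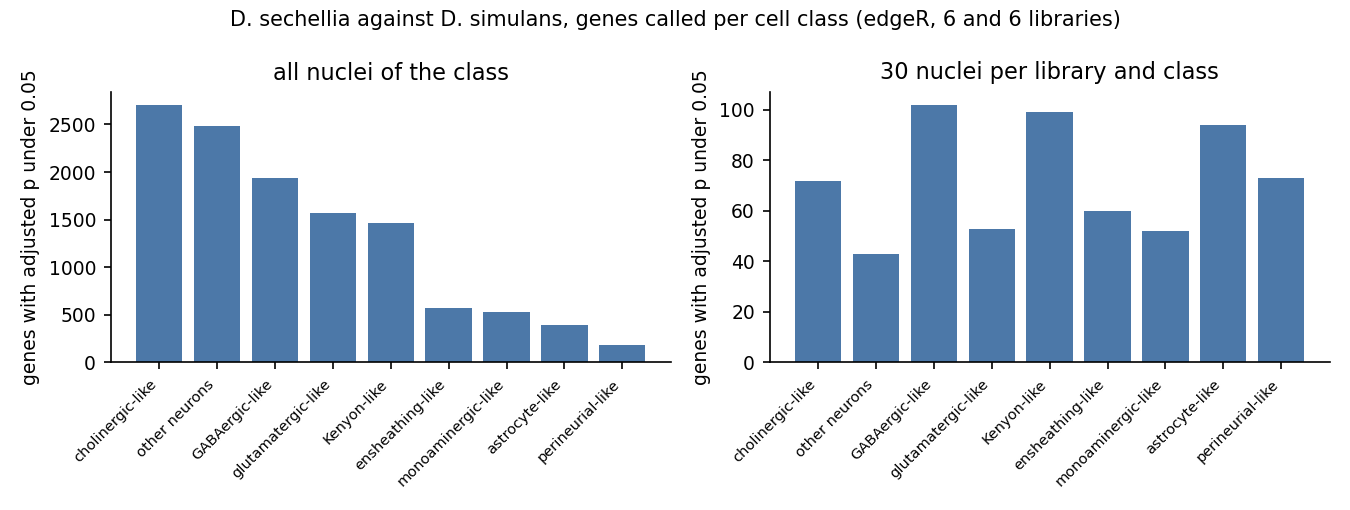
Genes called by edgeR between D. sechellia and D. simulans (y axis) in each cell class (x axis), with all nuclei of the class (left) and with 30 nuclei per library and class (right). The bar of cholinergic-like neurons stands at 2705 on the left and at 72 on the right, and that of perineurial-like glia at 180 and 73.

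The interaction test asked whether a species difference differs between glia and neurons. It called 448 of 8306 genes. The log2 fold change in glia minus that in neurons was positive for 238 of them and negative for 210. This sign does not tell in which kind of cell the species differed more. It called 145 with equal numbers of glial and neuronal nuclei, 223 in replicates 1 to 4 and 311 in replicates 5 and 6. Ddr stood at 1015 CPM in glia of D. sechellia and 91.9 in those of D. simulans, and at 271 and 270 in neurons. The gene myo, which encodes a TGF-beta family ligand, stood at 504 and 421 CPM in glia but at 6.89 and 46.0 in neurons. The dpy gene moved in opposite directions, with log2 fold changes of -2.82 in glia and 1.07 in neurons.

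**Figure D3:**
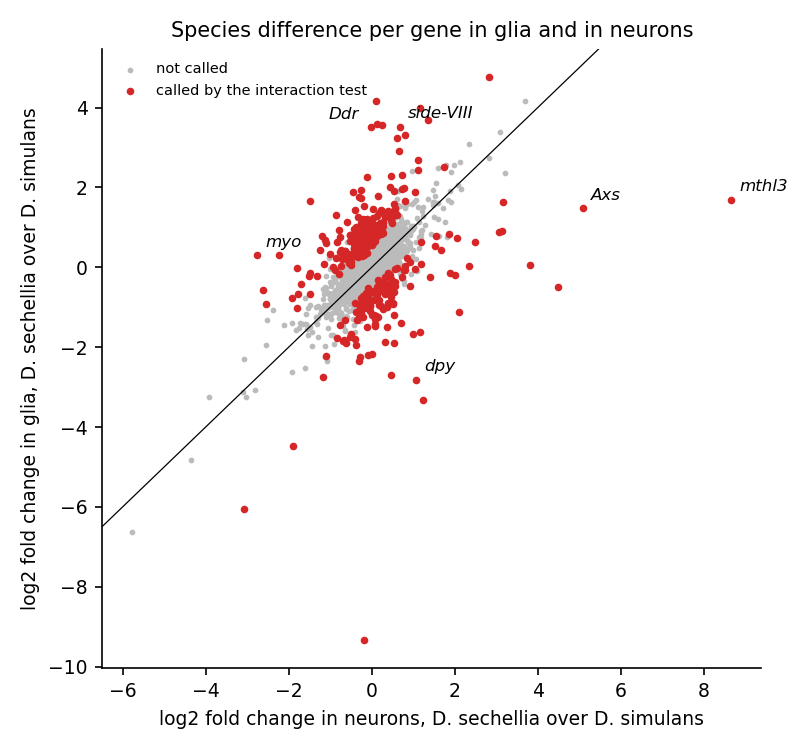
Log2 fold change of D. sechellia over D. simulans in glia (y axis) against that in neurons (x axis); each point is a gene with both values, red points are called by the interaction test, and the line marks equal changes. Ddr lies at 3.50 in glia and -0.02 in neurons, and mthl3 at 1.69 and 8.66.

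The comparison of D. sechellia on noni with D. sechellia on standard food asks whether the diet changes the brain of adult flies. The dopamine synthesis genes Ddc and ple, and Catsup, lay within the spread of the libraries. Catsup stood at 11.2 ± 2.13 CPM on noni and 10.1 ± 1.31 on standard food, Ddc at 745 ± 84.3 and 694 ± 95.5, and ple at 46.3 ± 9.66 and 46.2 ± 6.11 (SD, n = 6). The neuronal gene elav stood at 857 ± 96.5 and 891 ± 96.7, and the glial gene repo at 9.18 ± 1.17 and 9.46 ± 1.67. Being scaled to the whole table, these levels cannot be compared with those of the species comparisons. edgeR called 0 of 9237 genes, with 68 at an unadjusted p under 0.05, and DESeq2 called 0. With the replicate block edgeR called 0, with 273 at an unadjusted p under 0.05. In replicates 1 to 4 it called 0, with 62, and in replicates 5 and 6 it called 0, with 121. Chance alone would put a share of 0.05 of the genes under that value, more than any of these whole-brain counts. The tests were thus likely conservative in these libraries, and 0 calls do not exclude a change with diet. In each of 9 classes edgeR called 0 genes, with 118 in GABAergic-like, 116 in Kenyon-like, 79 in cholinergic-like, 131 in glutamatergic-like, 81 in monoaminergic-like and 100 in other neurons at an unadjusted p under 0.05, and 29 in astrocyte-like, 72 in ensheathing-like and 22 in perineurial-like glia. The interaction test by edgeR called 0 of 9132, with 256 at an unadjusted p under 0.05, and DESeq2 called 0. In replicates 5 and 6 alone, edgeR called 2 genes in glutamatergic-like neurons and 1 by the interaction test.

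Class shares were close between the diets. Perineurial-like glia made up 0.567% ± 0.0857 of nuclei on noni and 0.569% ± 0.178 on standard food, Kenyon-like neurons 8.80% ± 1.34 and 9.39% ± 1.13, and astrocyte-like glia 1.83% ± 0.391 and 1.63% ± 0.436 (SD, n = 6). The lowest exact adjusted p over the 12 classes was 0.959. Among gene lists, camera with its preset correlation called oxidative phosphorylation higher on noni (69 members, median log2 fold change of 0.07, adjusted p = 9.04e-10), neuropeptides higher (38 members, median 0.12, adjusted p = 1.03e-04) and IgSF molecules lower (64 members, median -0.06, adjusted p = 0.00196). No member of these lists was called by edgeR, over all genes or adjusted over the list alone. Each list had an adjusted p = 0.699 with an estimated correlation and 0.859 by fry. With the replicate block camera called 7 lists, these 3 and, higher on noni, ribosomal proteins (adjusted p = 0.0177), heat shock genes (0.0117), transmitter recycling (0.0421) and yolk and fat body genes (0.00211). With an estimated correlation, which was run without the block only, the adjusted p was 0.739 for ribosomal proteins and 0.699 for the other 3. In simulated libraries, 54% of 1.5-fold changes and 6% of the smallest changes planted were recovered in whole brains. These libraries lacked the resemblance by replicate number, so recovery in the real ones may differ.

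The comparison of D. sechellia with D. melanogaster sets the specialist against the reference species, with a gene table for each. The dopamine receptor gene Dop2R was lower in D. sechellia, at 131 ± 9.99 CPM against 4412 ± 674 (log2 fold change of -5.23, edgeR adjusted p = 2.93e-17), as were Dop1R1 at 186 against 425, the muscarinic receptor gene mAChR-A at 97.2 against 414, nAChRalpha1 at 354 against 1050.0 and nAChRalpha3 at 208 against 736. Potassium channel genes Hk (-1.67) and Shal (-1.81) and the synaptic genes nSyb (-1.01), Syn (-0.83) and shi (-0.89) were lower, as were the neuropeptide receptor genes AstC-R1 (-3.99) and SPR (-1.73), the hormone genes Gpb5 (-3.2) and Ilp5 (-2.32) and the glycolysis genes Eno (-2.61) and Ald1 (-1.22). Ddc stood at 797 ± 105 CPM against 1701 ± 165 and CrebB, a memory-related transcription factor gene, at 19.5 against 88.7. Higher in D. sechellia were ple (0.55), elav (0.73), RpL22 (1.51) and the adhesion gene beat-IIIa, at 158 ± 12.9 CPM against 0.228 ± 0.141. The odorant receptor gene Or42a had a ratio of 5950 (1070 to 235000). The genes repo (edgeR adjusted p = 0.275) and Catsup (0.6) did not pass.

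Several genes had counts in 1 of these species alone. stnB was at least 22980-fold, stnA at least 3758-fold and Prx5 at least 11810-fold higher in D. sechellia, and Ggamma30A was at least 72040-fold, gprs at least 8355-fold and eEF5 at least 3341-fold lower. stnA and stnB lie on 1 dicistronic transcript, which makes their separate counts uncertain. NFAT stood at 0.84 ± 0.276 CPM against 640 ± 28.8 (SD, n = 6). edgeR called 5760 of 8716 genes, 2989 higher and 2771 lower, of which 1220 and 1081 differed at least 2-fold; it called 5335 in replicates 1 to 4 and 4752 in replicates 5 and 6, where 89 and 87 of the 91 genes named by the rule kept their side of the threshold and 0 reversed. Chemosensory receptors were the list camera called, upward, with 28 of 43 higher and 6 lower (28 and 6 adjusted over the list alone; adjusted p = 0.00325, and adjusted p = 0.945 with an estimated correlation). The mitochondrially encoded gene mt:CoI was listed at 0 in every D. sechellia and D. simulans library, all counted on the shared table, against 371 CPM in D. melanogaster, so its value reflects the counting and not the species. For the other genes the species and the gene table cannot be told apart.

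Glia made up a smaller share of kept nuclei in D. sechellia than in D. melanogaster. Astrocyte-like and ensheathing-like nuclei held medians of 650 and 774 UMIs over all groups, near the minimum of 500. Barcode medians ran from 1316 to 1843 UMIs in D. sechellia libraries and from 1497 to 2303 in those of D. melanogaster. Of perineurial-like nuclei 27.1% and 20.1% lay under 700 UMIs (exact permutation p = 0.195). More glial nuclei lost below the minimum in D. sechellia cannot therefore be told apart from fewer glia. Perineurial-like nuclei made up 0.569% ± 0.178 against 1.38% ± 0.232, with an exact adjusted p of 0.026 (n = 6), and the share was lower in 6 of 6 same-numbered pairs. Astrocyte-like nuclei made up 1.63% ± 0.436 against 2.40% ± 0.418 and ensheathing-like nuclei 2.67% ± 0.648 against 3.77% ± 0.553, each with an exact adjusted p of 0.039. Other neurons made up 27.0% ± 0.648 against 25.2% ± 0.888, also with an exact adjusted p of 0.039. Astrocyte-like and ensheathing-like shares were lower in 6 of 6 same-numbered pairs, and other neurons higher in 5. The paired exact sign-flip test with replicate number as a block passed no class after adjustment. Its smallest possible p passes only if many classes reach it. In replicates 1 to 4 and in replicates 5 and 6 the differences (D. sechellia vs D. melanogaster) were -0.722 and -0.975 percentage points for perineurial-like, -0.869 and -0.5745 for astrocyte-like, -1.2 and -0.903 for ensheathing-like nuclei and 1.88 and 1.7 for other neurons. Of the 10 leading genes of each cluster, 6 and 8 in the perineurial-like, 6 and 6 in the ensheathing-like and 8 in the astrocyte-like clusters were themselves called between these species. After clustering without such genes the difference was -0.792 for perineurial-like (exact adjusted p = 0.026), -0.776 for astrocyte-like and -1.11 for ensheathing-like nuclei and 3.11 for other neurons, and the last 3 no longer passed (0.0519, 0.0519 and 0.0584); other neurons then numbered 103638 nuclei instead of 53467. Among nuclei with at least 1000 UMIs astrocyte-like (-0.162, exact adjusted p = 0.113), ensheathing-like (-0.699, 0.109) and other neurons (0.399, 0.41) did not pass. With doublets kept astrocyte-like (-0.701) and ensheathing-like nuclei (-0.97) did not pass (exact adjusted p = 0.0649 each). Perineurial-like nuclei passed under both of these settings. On leaving out each of 12 libraries in turn, astrocyte-like nuclei and other neurons missed the threshold in 8 sets. Ensheathing-like nuclei missed it in 9 and perineurial-like nuclei in 3.

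D. simulans was compared with D. melanogaster to show differences that involve a generalist on both sides. Dop2R stood at 126 ± 15.96 CPM in D. simulans and 4412 ± 674 in D. melanogaster (log2 fold change of -5.28, edgeR adjusted p = 3.04e-17), Dop1R1 at 188 against 425 and mAChR-A at 77.5 against 414. The potassium channel genes Hk (-1.76), Shal (-2.22) and Sh (-1.23) were lower, with Sh at 2846 against 6044 CPM. Also lower were nSyb (-0.82), AstC-R1 (-4.18), SPR (-2.05), the tachykinin gene Tk (-3.21), Gpb5 (-2.76), Eno (-2.41), SdhA (-1.5), the septate junction gene Nrx-IV (-2.36), the clock gene Clk (-1.46), CrebB (-2.46) and Ddc (-1.26). LanB2 stood at 113 ± 18.4 CPM against 0.686 ± 0.321, Ir67b at 22.8 ± 9.28 against 0.0359 ± 0.0412, beat-IIIa at 189 ± 14.2 against 0.228 ± 0.141, RpL22 at 352 ± 36.9 against 83.9 ± 20.8 and RpS26 at 386 ± 50.3 against 202 ± 35.0 (SD, n = 6). Or42a had a ratio of 6130 (1100 to 242000), stnB was at least 29140-fold higher and Ggamma30A at least 72860-fold lower. ple was higher by 0.46 and elav by 0.40, repo did not pass (edgeR adjusted p = 0.124), and Catsup was lower (-0.26, 0.0225) but did not pass without D. melanogaster replicate 3 (0.067) or D. simulans replicate 5 (0.053).

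edgeR called 5594 of 8716 genes between D. simulans and D. melanogaster, 2926 higher and 2668 lower, of which 1072 and 1082 differed at least 2-fold. It called 5052 in replicates 1 to 4 and 4574 in replicates 5 and 6, where 86 and 84 of the 91 genes named by the rule kept their side of the threshold and 0 reversed. Chemosensory receptors were called upward by camera (22 higher and 5 lower of 43, and the same adjusted over the list alone; adjusted p = 0.0135, and adjusted p = 0.964 with an estimated correlation). Ensheathing-like nuclei made up 2.63% ± 0.438 against 3.77% ± 0.553 (exact adjusted p = 0.026, n = 6) and glutamatergic-like neurons 9.65% ± 0.376 against 9.07% ± 0.277 (exact adjusted p = 0.026). Neither passed as a ratio to neurons (exact adjusted p = 0.0519 and 0.268) or at the higher Leiden resolution (0.0519 and 0.4), and ensheathing-like nuclei did not pass among nuclei with at least 1000 UMIs (0.0952). Without D. simulans replicate 6 the glutamatergic-like difference was 0.42 percentage points and did not pass (exact adjusted p = 0.0519), although the libraries of the 2 species still did not overlap; the ensheathing-like one did not pass without D. simulans replicate 1, 2, 4, 5 or 6 (up to 0.0649). After clustering without the leading genes that differed between species, ensheathing-like nuclei did not pass (-1.14, 0.0606) and the glutamatergic-like difference was -0.0183, in a class of 3637 nuclei, 2850 of them among the 19088 first given that name. In replicates 1 to 4 and in replicates 5 and 6 the differences (D. simulans vs D. melanogaster) were -1.05 and -1.3 percentage points for ensheathing-like nuclei and 0.359 and 0.996 for glutamatergic-like neurons. Perineurial-like nuclei, at 1.05% against 1.38%, missed the threshold (exact adjusted p = 0.052, n = 6). Ensheathing-like shares were lower and glutamatergic-like shares higher in 6 of 6 same-numbered pairs. The paired exact sign-flip test with replicate number as a block passed no class after adjustment.

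The distance of each brain class from D. melanogaster was larger in D. sechellia than in D. simulans in all 9 classes, by 0.0019 in ensheathing-like glia to 0.0134 in perineurial-like glia. The ensheathing-like difference depended on single libraries, being -0.000149 without D. sechellia replicate 4, 0.000785 without D. sechellia replicate 2, 0.00112 without D. melanogaster replicate 2, 0.00122 without D. simulans replicate 2, 0.00125 without D. sechellia replicate 5 and 0.00305, 0.00348 and 0.00309 without D. sechellia replicates 1, 3 and 6; without D. simulans replicate 2 that of other neurons was 0.0122 instead of 0.0076. In glutamatergic-like neurons it was 0.234 ± 0.00499 in D. sechellia and 0.222 ± 0.00727 in D. simulans (SD, n = 6; exact permutation p = 0.00649, 0.0584 adjusted). The exact adjusted p was under 0.05 in 0 classes, with 1 at an unadjusted p under 0.05. All 9 differences were also positive in replicates 1 to 4, with none past the threshold, and in replicates 5 and 6, where the smallest exact p of 2 against 2 libraries is 0.333 and none could pass. The differences depended on depth. With equal UMIs as well as equal nuclei they ran from 0.00212 in astrocyte-like to 0.00765 in GABAergic-like nuclei, with 0.00609 in glutamatergic-like and 0.00586 in perineurial-like nuclei, and the exact adjusted p was under 0.05 in 4 classes. At the smallest number of nuclei of a class in all libraries they ran from 0.00249 in ensheathing-like to 0.0131 in perineurial-like nuclei. There cholinergic-like nuclei had 0.00344 instead of 0.0113, and 6 classes passed. D. sechellia and D. simulans share 1 gene table, and the genome or genomes behind it are not given. A difference between them in read assignment could therefore enter the distance of every class, also at equal depth. The 9 classes come from the same libraries, so their shared direction is not independent evidence.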

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

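The counts of other splits for whole brains and for gene lists, the test on the fat body-like share, the count of genes outside the interaction and the use of the estimated correlation as a test were chosen after the results had been seen, and the other tests were set before. Among 244 sets of 6 libraries (class shares, totals and the levels of genes named in the text), 17 held a library set apart from the other 5, where chance gives about 1 in 20. Cortex-like glia stood out in replicate 1 of 3 groups, with 0.949% of nuclei in D. simulans (others 0.273% to 0.431%), 1.24% in D. sechellia on standard food (0.011% to 0.367%) and 1.19% on noni (0.018% to 0.414%). These shares are in no comparison that passed. Glutamatergic-like neurons stood at 10.4% in D. simulans replicate 6 (others 9.38% to 9.56%), and neuroendocrine-like neurons at 0.264% in D. melanogaster replicate 5 (others 0.371% to 0.432%). Single libraries also stood apart in CPM for AstC-R1 (30.0 in D. melanogaster 1), Or42a (0.0553 in D. melanogaster 2) and ple (27.1 in D. melanogaster 6). In D. simulans these were beat-IIIa (161 in library 2), Pvf1 (1.19 in library 3), RpL5 (209 in library 5) and Catsup (11.8 in library 6). In D. sechellia they were GlyT (105) and shi (486) in library 1, Gs1 (114) in library 2, and GstD9 (22.3) and nAChRalpha3 (156) in library 5.

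Between D. sechellia and D. simulans, 6 genes were singled out because the species difference itself differed between glia and neurons by the interaction test. mthl3 differed more in neurons (log2 fold change of 8.66) than in glia (1.69), by -6.97, as did Axs (5.08 and 1.48), by -3.64. Ddr differed in glia (3.50) and not in neurons (-0.02), by 3.47, and side-VIII more in glia (3.52) than in neurons (0.67), by 2.82. myo was lower in neurons (-2.77) but not called in glia (0.30), by 3.03. dpy went in opposite directions, by -3.85.

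The first pattern weighed is the lower perineurial-like share of D. sechellia. If such nuclei had been placed in other classes, those with UMIs of at least 2 perineurial markers outside the class would be more frequent in D. sechellia. They differed by -0.0402 percentage points (exact permutation p = 0.251), and within the class 42.4% and 55.8% had such UMIs. This argues against misplaced nuclei that carry these UMIs as often as the class does. The same markers named the class, so misplaced nuclei with weaker markers would be missed and stay open. Loss of small nuclei below the UMI minimum stays open: the part of the class under 700 UMIs differed by -1.67 percentage points (exact p = 0.723, n = 6), a test that could not see nuclei already removed. Loss of the brain surface in dissection cannot be told apart either, since the fat body-like share differed by -0.0999 percentage points (exact p = 0.455), within a spread too wide to decide. A smaller perineurial layer in D. sechellia may also underlie the share and was not tested.

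The second pattern is the large number of genes called between D. sechellia and D. simulans, which share a gene table. If reads of a gene were gained or lost by 1 factor per species, the difference would be equal in glia and neurons. For 448 genes it was not (145 with equal numbers of glial and neuronal nuclei), against 23 at most in other splits of the full data, so such a factor cannot be the whole cause there. Of the 448, 327 were tested in both kinds of cell, with 106 past the threshold in both, 40 of these in opposite directions. For the 3203 whole-brain calls that the interaction did not call, mapping and expression cannot be told apart. Transcripts that differ in their ends between glia and neurons could produce an interaction through mapping as well. Glia were summed over classes, and perineurial-like nuclei made up 0.569% of kept nuclei in D. sechellia and 1.05% in D. simulans. A different mix of glial classes could therefore also give an interaction, and was not tested. No background RNA was subtracted, so glial values also hold RNA of other cells, and its part in the interaction was not tested.

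The third pattern is the lists called between the diets. Genes of a list that rise and fall together between libraries of a group would give such calls, and with the correlation estimated from the data 0 of 3 lists stayed past the threshold. Among 100 splits of the 12 libraries, 89 gave at least as many lists, up to 15, and among the 32 that part every same-numbered pair 29 did, up to 14, so chance cannot be excluded; with the replicate block 7 lists were called, for which no splits were counted. The same holds for the list calls of D. sechellia and D. simulans (86 of 100, up to 12), D. sechellia and D. melanogaster (93, up to 12) and D. simulans and D. melanogaster (86, up to 13). A response of these genes to noni is not excluded and was not tested further.

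Other splits of the libraries were counted for each gene test. For whole brains the real split was the only 1 of 100 with as many genes between D. sechellia and D. simulans (3673, highest other 565), D. sechellia and D. melanogaster (5760, 2692) and D. simulans and D. melanogaster (5594, 2038). A random split is thus unlikely to give such counts. Other splits mix the species within a group, which widens the spread and lowers their counts, so they do not vouch for single genes. Between the diets the real count was 0, which all 100 splits match by definition, so their number decides nothing. The highest other, 1129, set replicates 1 to 3 of both diets against the rest, which points to a structure of the libraries by replicate number. Among the 32 splits that part every same-numbered pair, as the real split does, the highest others were 0 between the diets, 399 for D. sechellia and D. simulans, 2148 for D. sechellia and D. melanogaster and 2038 for D. simulans and D. melanogaster; the remaining splits keep some pairs together. In each of 9 classes the real split was the only 1 of 40 with as many genes for every pair of species. Real counts and highest others ran from 180 and 38 in perineurial-like to 2705 and 263 in cholinergic-like nuclei for D. sechellia and D. simulans, from 610 and 107 to 4691 and 1674 for D. sechellia and D. melanogaster, and from 657 and 9 to 4480 and 1470 for D. simulans and D. melanogaster. A share of 1 of 40 is the smallest that this test can give, and it was run in many classes. Between the diets the real count was 0 in each class, which all 40 splits match by definition, and no split called more than 1 gene. For the interaction the real split was the only 1 of 60 between D. sechellia and D. simulans, while between the diets 60 of 60 splits called 0 genes.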

How the results depend on the processing

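The sets limited to a range of replicate numbers and the clusterings on other genes were chosen after the data had been seen. So were the D. simulans and D. sechellia table as a whole and 3 of the distance settings. The other alternatives were planned. The whole-brain counts stayed within 1.5 times their value in every alternative, with the replicate block giving 4743 genes between D. sechellia and D. simulans, 6516 between D. sechellia and D. melanogaster and 6342 between D. simulans and D. melanogaster, and leaving out single libraries giving 3440 to 3694, 5614 to 5782 and 5424 to 5589. The diet comparison stayed at 0 (edgeR and DESeq2), with up to 273 at an unadjusted p under 0.05. Of the named genes, 63 of 87, 87 of 91 and 82 of 91 kept their side of the threshold in all alternatives, and 0 reversed.

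Fewer nuclei called fewer genes. With 30 nuclei per library and class, D. sechellia and D. simulans differed in 648 genes summed over classes (GABAergic-like 102, Kenyon-like 99, astrocyte-like 94, perineurial-like 73, cholinergic-like 72, ensheathing-like 60, glutamatergic-like 53, monoaminergic-like 52, other neurons 43). D. sechellia and D. melanogaster differed in 3128 (480, 353, 193, 220, 452, 208, 403, 413 and 406 in the same order), and D. simulans and D. melanogaster in 3092 (482, 363, 167, 204, 459, 188, 405, 417 and 407). With equal numbers of glia and neurons the interaction called 145 genes, while it called 223 in replicates 1 to 4 and 311 in replicates 5 and 6. In replicates 5 and 6, D. sechellia and D. simulans differed in 6591 genes summed over classes (1110, 904, 213, 60, 1649, 262, 754, 214 and 1425 in that order), D. sechellia and D. melanogaster in 781 in ensheathing-like and 349 in perineurial-like nuclei, and D. simulans and D. melanogaster in 963 in monoaminergic-like and 367 in perineurial-like nuclei. The diets differed there in 2 genes, both in glutamatergic-like neurons, and in 1 by the interaction. The replicate block called 287 genes in perineurial-like nuclei between D. sechellia and D. simulans.

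Class shares changed under several settings, and the cause was not tested. With at least 1000 UMIs, the perineurial-like difference of D. sechellia and D. simulans was -0.194 percentage points (0 classes called), those of D. sechellia and D. melanogaster were -0.162 (astrocyte-like), -0.699 (ensheathing-like) and 0.399 (other neurons; 2 classes called), and the ensheathing-like one of D. simulans and D. melanogaster was -0.709 (1 class called). With doublets kept, D. sechellia and D. melanogaster had -0.701 (astrocyte-like) and -0.97 (ensheathing-like; 2 classes called), and D. simulans and D. melanogaster 4 classes. Clustered without leading genes called between species, perineurial-like D. sechellia and D. simulans had -0.335 (0 classes), D. sechellia and D. melanogaster -0.776, -1.11 and 3.11 for astrocyte-like, ensheathing-like and other neurons (1 class), and D. simulans and D. melanogaster -1.14 (ensheathing-like) and -0.0183 (glutamatergic-like, reversed; 0 classes). Clustered without any gene called between D. sechellia and D. simulans, the glutamatergic-like difference was -0.222, also reversed, D. sechellia and D. melanogaster had 7 classes, and the perineurial-like difference (D. sechellia vs D. simulans) was -0.448 (exact adjusted p = 0.026). At the higher Leiden resolution D. simulans and D. melanogaster had -1.13 and 0.355, and as a ratio to neurons -1.3 and 0.44 (0 classes each), and in replicates 5 and 6 the glutamatergic-like difference was 0.996.

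Leaving out single libraries gave 0 to 1 classes for D. sechellia and D. simulans, with the perineurial-like difference from -0.522 to -0.447 and an exact adjusted p of 0.026 to 0.0779; it missed the threshold without any 1 of the 6 D. simulans libraries (0.0519 or 0.0779) and passed without any 1 of D. sechellia. The libraries of the 2 species did not overlap in any of these sets, so the loss came from assignments with the opposite sign that groups of unequal size allow. D. sechellia and D. melanogaster had 0 to 5 classes, with -0.899 to -0.653 (astrocyte-like) and 1.63 to 2.08 (other neurons), each missed without D. melanogaster 2, 3, 4 or 6 or D. sechellia 1, 2, 5 or 6, -1.29 to -0.91 (ensheathing-like, missed without these or D. melanogaster 5), and -0.884 to -0.752 (perineurial-like, missed without D. sechellia 2, 5 or 6, for the same reason). D. simulans and D. melanogaster had 0 to 4 classes, with -1.26 to -0.997 (ensheathing-like, missed without D. simulans 1, 2, 4, 5 or 6) and 0.42 to 0.624 (glutamatergic-like, missed without D. simulans 6, for the same reason). The classes past the threshold with a larger distance in D. sechellia numbered 1 with Spearman correlation, 4 with equal nuclei and UMIs, 6 with the smallest number of nuclei of a class, 6 with that and equal UMIs, and 0 to 3 on leaving out libraries (changed without D. melanogaster 4 or 6, D. simulans 2 or D. sechellia 3). Of 7 list calls in all, 0 stayed with an estimated correlation; fry made 34 (14 for D. sechellia and D. melanogaster, 10 for each of the other species pairs, 0 for the diets) and the replicate block 12, 7 of them between the diets.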

Other observations

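The tests within classes below were planned, and no explanation was tested for them. Ribosomal protein genes were lower in D. sechellia than in D. simulans within most brain cell classes by camera with its preset correlation. In Kenyon-like neurons the adjusted p was 2.05e-14 (adjusted p = 0.751 with an estimated correlation), in GABAergic-like neurons 5.02e-10 (0.553), in cholinergic-like neurons 8.98e-08 (0.876), in astrocyte-like glia 3.34e-05 (0.969) and in ensheathing-like glia 0.000132 (0.864). Perineurial-like glia did not pass (0.733). Nuclear genes of oxidative phosphorylation were lower as well, with adjusted p of 1.35e-09 in GABAergic-like neurons (0.52 with an estimated correlation), 7.93e-05 in monoaminergic-like neurons (0.435) and 0.0312 in astrocyte-like glia (0.969), and no call in perineurial-like glia (0.383).

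Within glia, further genes separated D. sechellia from D. simulans. In perineurial-like nuclei the opsin gene Rh7 stood at 495 ± 206 CPM against 32.4 ± 16.9 (SD, n = 6; edgeR adjusted p = 1.2e-06; 13.5 and 6.74 in whole brains) and Unc-89 at 33.8 against 227 (0.295 and 2.16 in whole brains). No background RNA was subtracted: the neuronal gene elav stood at 482 and 614 CPM in perineurial-like nuclei against 1023 and 807 in whole brains, so a glial level at or below that of whole brains cannot be assigned to glia. In ensheathing-like nuclei dob had a ratio of 78.4 (21.4 to 652), while ec stood at 5.39 against 119 CPM and Ugt35B1 at 23.8 against 266. In astrocyte-like nuclei GILT2 was at least 16.6-fold lower. In neurons, myo stood at 3.96 ± 1.49 CPM in GABAergic-like nuclei of D. sechellia against 38.7 ± 6.81, alpha-Est8 in Kenyon-like nuclei at 3.90 against 45.8, and IRSp53 in glutamatergic-like nuclei at 2.94 against 26.9. Perineurial-like glia of noni-fed flies did not differ detectably from those on standard food, where 66% of simulated 4-fold changes were recovered.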
